A study of Mus musculus with 4 samples.

How the data were processed

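RNA was sequenced from fetal liver cells of 2 mice labelled wild-type and 2 labelled as knockouts of hnRNP L (heterogeneous nuclear ribonucleoprotein L), an RNA-binding protein that acts in splicing. Per the labels' protocols, ribosomal RNA was depleted from total RNA, the RNA was cut with RNase III, fragments of 150 to 300 bp were amplified for 12 PCR cycles, and the 4 barcoded libraries were sequenced as beads on 2 slides with 2 libraries on each. Which libraries shared a slide is not given in the sources used here, so slide and genotype cannot be separated. The labels name each sample only as a mouse of its genotype. They give no litter, and the p-values measure the spread between these 4 libraries. The kind of deletion and the embryonic day are not given in the sources used here.

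For each library the authors deposited a table of RefSeq transcripts with the raw count of reads per transcript. Per the file headers, only primary alignments with a mapping quality of at least 10 were counted, with a score clear zone of 5 and a minimum score of 0. The same tables hold, per the file headers, RPKM values made by the authors from the mapped reads of the library, and the deposited reads per nucleotide, a coverage signal equal to the read count over transcript length. Both were recomputed from the counts and matched in 100% of rows, and neither entered a test. A second deposited table per library gives the raw count of reads across each of 1921627 splice junctions, of which 186874 are marked as known and 1734753 as putative, and 201779 had a read in at least 1 library. The aligner, the genome build and the rules of junction counting are not given in the sources used here. Gene coordinates are printed as the files give them and are not those of GRCm38: only 151 of 21529 genes that could be compared had the same start and end. Strand-specific counting is not stated, so overlapping and antisense genes can share reads. Close copies such as the adult beta globins and the histone genes can share reads too, and their single values are less certain.

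The 28283 transcript rows were reduced to 22011 genes by keeping, for each of the 3809 genes with several transcripts, the transcript with most reads over the 4 libraries, since each isoform has its own count and a sum could count a shared read more than once. No row lacked a gene name. Mapped reads, per the file headers, numbered 70020061 and 111324295 in the wild-type libraries and 97490949 and 96260423 in the knockout libraries, and 33738842, 56895360, 47700332 and 48162924 reads fell on the transcripts used. The 10 most abundant genes took 11.3% to 13.5% of these reads.

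Gene levels were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the raw counts, with TMM scaling, the default filter of filterByExpr, and Benjamini-Hochberg adjustment over 15028 genes. The threshold was an adjusted p of 0.05. Values are counts per 1000000 reads (CPM) on TMM-scaled library sizes, as mean ± SD with n = 2 per group, and fold changes are knockout over wild type. The standard error of a log2 fold change was computed as its size divided by the square root of the F statistic. With 2 libraries against 2, an exact two-sided permutation test cannot give a p below 0.333, so calls rest on the spread that edgeR pools over genes.

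Before the data were examined, 28 gene lists, the tests and the rule for named genes were fixed. Lists were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, and again with an estimated correlation and with fry, which tests a list by itself. With an estimated correlation, camera takes its degrees of freedom from the residuals of the 4 libraries. These are few, so few lists can pass that test whatever their correlation. Counts of members past the gene test are given over all genes and adjusted over the list alone. The rule named Hnrnpl; the 12 largest rises and the 12 largest falls among genes past the threshold with a mean log2 CPM of at least 2 and both knockout libraries beyond both wild-type libraries; and the 4 members with the smallest p of each list that passed its test, or 2 of each other list. It also named up to 12 junctions past the threshold with at least 20 reads and usage of both knockout libraries beyond both wild-type libraries, at most 1 per gene. Junctions of a set of target genes were named too, because hnRNP L or its paralog is known to control their splicing or because they act on p53. Only part of the genes so named are described. Lists of cardiac muscle, skeletal muscle and eosinophil genes were added after the data were seen. Of the listed symbols, 3 matched no gene in the files.

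Junction usage, the reads of a junction relative to the other junctions of its gene, was tested with diffSpliceDGE of edgeR on junctions with at least 10 reads over the 4 libraries in genes with at least 2 of them. Its coefficients are natural logs and were converted to log2. Genes were summarised by the Simes test. Shares of reads in a single library carry a 95% Wilson interval, and a count of 0 allows up to 3 reads. Intervals and floors cover counting error only, because PCR copies are not separate molecules.

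The tests were checked on simulated counts drawn from the means and library sizes of the real data. Dispersions were taken from their trend over abundance, and changed genes from those with a mean above 1 CPM. Genes that vary more than this trend were not simulated, so false calls may be more frequent in the real data. Among 15028 genes of which 100 were changed 2-fold and 100 by 1.5-fold, edgeR recovered 69% and 28% with 1 false call. For the gene lists, camera called 5 of 5 lists in which 10 of 20 members were changed by 1.5-fold and 0 of the others in 28. The simulated genes do not correlate, so this check says nothing on false calls in lists whose members vary together. In the junction test, 26% of 4-fold changes were recovered at 40 to under 400 reads and 64% at 400 reads or more. Of 2-fold changes it recovered 0% and 2%, with 3 false calls.

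Alternatives were DESeq2 size factors within edgeR, no filter on low counts, DESeq2 1.42.0, limma voom, the libraries without globin genes, a replicate block by a number that file names share, each library left out in turn, other minimum counts for junctions, and limma diffSplice. No mitochondrially encoded genes were removed with the globin genes, since the gene tables list none on the mitochondrial chromosome. The longest transcript per gene, junctions compared only with those of the same splice site, and the junction share without Speer genes were added after the data were seen. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.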

Results

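Transcripts and splice junctions were measured by RNA sequencing in fetal liver cells of mice labelled wild-type (WT, n = 2) and mice labelled as knockouts of the RNA-binding protein hnRNP L (KO, n = 2), to compare their gene levels and splicing. Fetal liver is the main site of blood formation before birth. Reads on known junctions numbered 4875332 and 8624429 in the WT libraries and 7150406 and 6941562 in the KO libraries. Log2 CPM of all tested genes correlated across genes at 0.986 between the WT libraries, 0.985 between the KO libraries and 0.969 to 0.972 between WT and KO libraries. KO replicate 2 had the Xist and Y-linked reads of a male and the other 3 libraries those of females. Xist had 31498, 51618, 45597 and 336 reads and Ddx3y 8, 14, 5 and 2839 reads in WT replicates 1 and 2 and KO replicates 1 and 2.

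The targeted gene, Hnrnpl (chromosome 7, 29595909 to 29607285, plus strand, build not given in the sources used here), was lower in both KO libraries. Its level was 460 and 603 CPM in the WT libraries and 280 and 269 CPM in the KO libraries, with means of 531 ± 101 (SD, n = 2) and 274 ± 7.56 (SD, n = 2). It fell by 0.95 on the log2 scale (SE 0.16, edgeR quasi-likelihood test, adjusted p = 0.0114), to 0.516 of WT. Reads remained on each of its 12 annotated junctions in KO. Reads across junctions 1 to 6 were at 0.559 of WT (580 ± 45.9 against 324 ± 4.94 per 1000000 known junction reads, SD, n = 2) and across junctions 7 to 12 at 0.506 (426 ± 35.7 against 215 ± 3.91, SD, n = 2). Junction 1 was at 0.281 of WT, with 31, 54, 12 and 13 reads in WT replicates 1 and 2 and KO replicates 1 and 2. The position of the deletion is not given in the sources used here. A deletion of whole exons would leave no reads on the junctions of those exons. Since reads remained on all 12 junctions, the KO libraries held transcript without such a deletion, wherever it lies. The loss of Hnrnpl transcript was thus partial in these libraries. The kind of deletion is not given either, so the remaining reads do not show whether hnRNP L protein or its function was lost. The source of the remaining transcript was not tested.

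**Figure D1:**
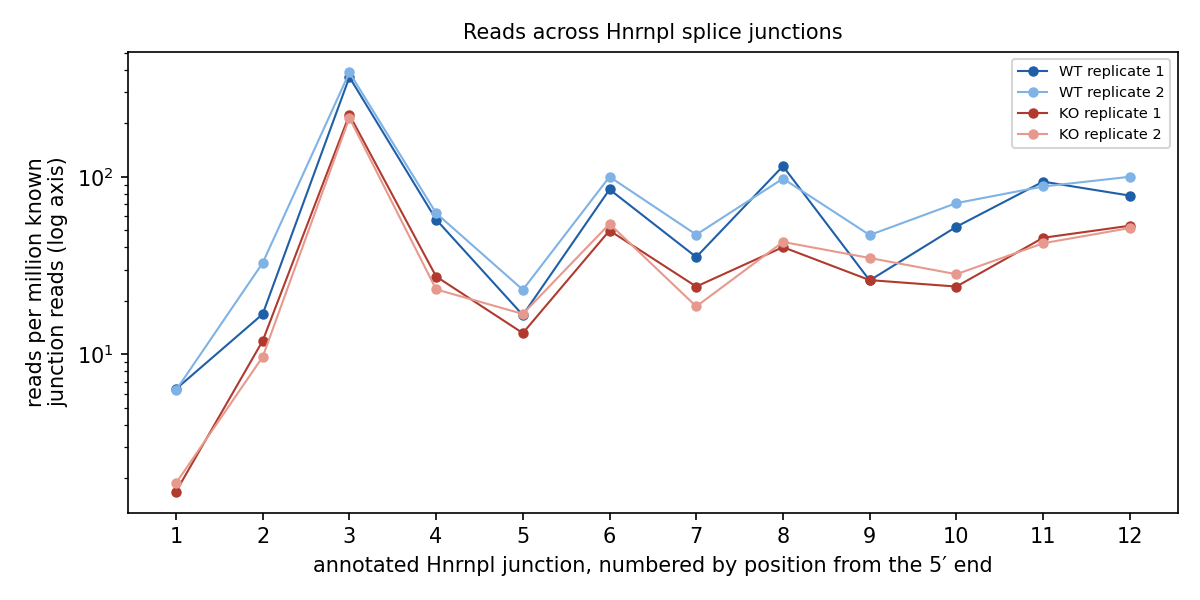
Reads across the 12 annotated Hnrnpl junctions per 1000000 known junction reads (y, log axis) by junction number from the 5′ end (x), with 1 line per library. Both KO libraries lie below both WT libraries at most junctions, and junction 1 is at 0.281 of WT.

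Target genes of the tumour suppressor p53 were 5 of the 12 largest rises. Cdkn1a (chromosome 17, 29230717 to 29237667), the cyclin-dependent kinase inhibitor p21, rose 17.4-fold from 5.96 ± 0.684 to 103 ± 10.1 CPM (SD, n = 2; edgeR adjusted p = 8.95e-05). Eda2r, a receptor of the tumour necrosis factor family, rose 14.8-fold from 1.23 ± 0.214 to 18.5 ± 0.855 CPM (SD, n = 2; edgeR adjusted p = 0.00075). Zmat3 rose 5.45-fold, Phlda3 4.76-fold, the death receptor gene Tnfrsf10b 4.59-fold and Trp53inp1 3.03-fold. Of 39 tested p53 targets, 22 were higher, 3 were lower and 14 did not pass the threshold; adjusted over the list alone, 25 were higher and 4 lower. Without WT replicate 1, 14 were higher. The 3 lower were Sesn1, Btg2 and the survival gene Bcl2l1, chosen after their values were seen, and the call of Bcl2l1 was lost without WT replicate 1, WT replicate 2 or KO replicate 2 (edgeR adjusted p of 0.0685 to 0.0897). All 3 calls were lost without WT replicate 1 or KO replicate 2, and 1 target was lower without WT replicate 2. The median log2 fold change was 0.57 (camera adjusted p = 1.42e-08; adjusted p = 0.417 with an estimated correlation). Trp53 itself was at 79.1, 133, 161 and 141 CPM and did not pass the threshold (edgeR adjusted p = 0.141).

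The other large rises included genes of platelets and granulocytes. Among the 12 largest were Selp, the adhesion receptor P-selectin (5.38-fold), Mmp9, a matrix metalloproteinase of neutrophils (4.97-fold), the costimulatory gene Cd80 (5.43-fold) and Epx, the peroxidase of eosinophils (4.58-fold). Tmtc1 rose 5.52-fold and 6530418L21Rik 7.36-fold.

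**Figure D2:**
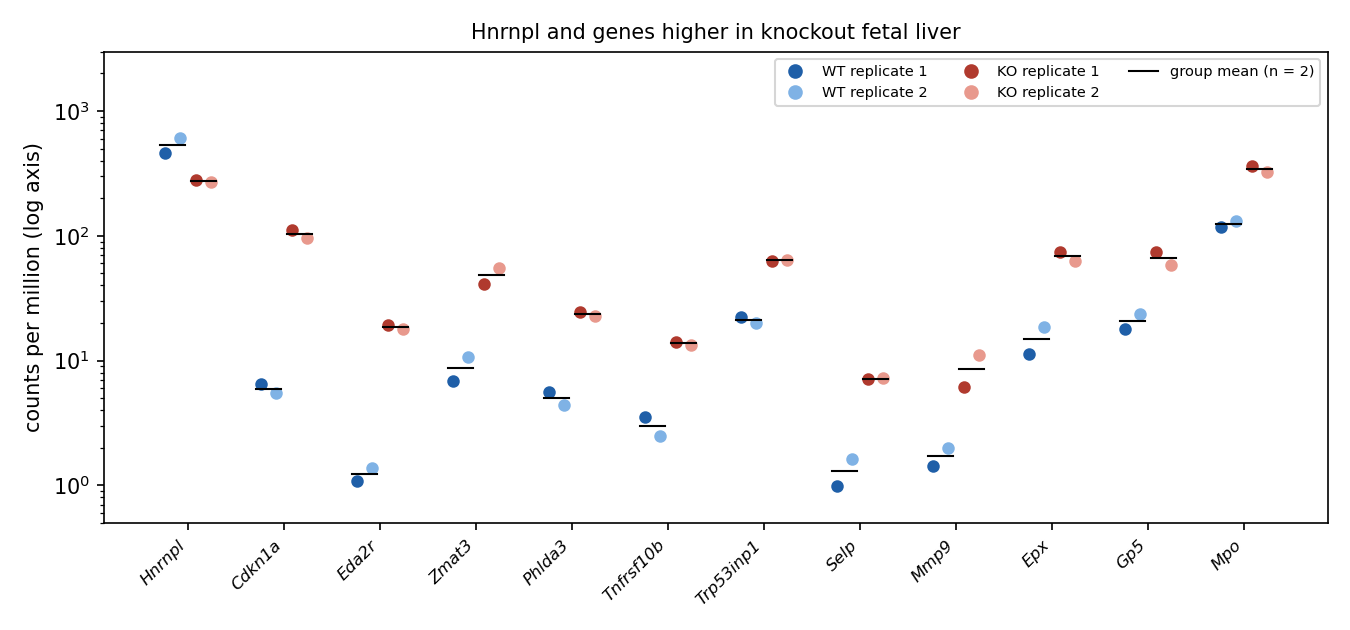
CPM (y, log axis) of Hnrnpl and 11 genes that were higher in KO (x), with 1 point per library and a bar at each group mean (n = 2). Cdkn1a has means of 5.96 CPM in WT and 103 CPM in KO, and no KO point overlaps a WT point.

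Over all genes, 3130 of 15028 (20.8%) passed the threshold of the edgeR test: 1711 were higher and 1419 lower in KO. More than 2-fold, 374 were higher and 168 lower. Both KO libraries lay beyond both WT libraries in 65.2% of genes, against 33.3% by chance. The count was 1616 without WT replicate 1, 1105 without WT replicate 2 and 1022 without KO replicate 2.

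Lists of S phase, G2/M, histone and repair genes had negative medians. Of 30 S phase genes, 22 were lower and 0 higher (25 lower adjusted over the list alone), with a median log2 fold change of -0.54 (camera adjusted p = 9.85e-13). E2f1, a transcription factor of S phase entry, fell to 0.544 of WT (edgeR adjusted p = 0.00716), and the DNA polymerase gene Pola1 to 0.601, from 116 ± 0.0181 to 69.8 ± 0.0602 CPM (SD, n = 2). Of 33 G2/M genes, 27 were lower (30 adjusted over the list alone; median -0.62, camera adjusted p = 2.26e-14), among them Nusap1 at 0.517 and Cenpf at 0.544 of WT. Of 31 replication-dependent histone genes, 21 were lower (28 adjusted over the list alone; median -0.92, and -1.43 without KO replicate 1; camera adjusted p = 2.24e-13). Hist1h1a, a linker histone, fell from 3438 ± 371 to 1517 ± 163 CPM (SD, n = 2). Of 30 genes of the DNA damage response and repair, 14 were lower (17 adjusted over the list alone; median -0.35, camera adjusted p = 5.91e-08), among them Brca2 at 0.522, Fanci at 0.631 and Chek2 at 0.623 of WT. With an estimated correlation, adjusted p = 0.417 for each of these 4 lists. Without KO replicate 2 the lower members numbered 8 in S phase, 9 in G2/M, 11 among histones and 4 in repair, and without WT replicate 2 they numbered 9, 13, 11 and 3. G2/M genes numbered 16 without WT replicate 1 and repair genes 9 without KO replicate 1.

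The erythroid list and the list of heme synthesis and iron also had negative medians. Of 33 erythroid genes, 21 were lower and 1 higher (27 and 2 adjusted over the list alone), with a median of -0.70 (camera adjusted p = 1.05e-10; adjusted p = 0.417 with an estimated correlation). Spna1, erythroid alpha spectrin, fell to 0.484 of WT and the water channel Aqp1 to 0.502. The 1 higher member was Spnb2, a spectrin also found in many other cells (1.81-fold). Of 23 genes of heme synthesis and iron, 12 were lower (15 lower and 2 higher adjusted over the list alone; median -0.52, camera adjusted p = 4.44e-06; adjusted p = 0.439 with an estimated correlation), among them Urod at 0.486 and Slc25a38 at 0.571 of WT. The lower members numbered 10 erythroid and 3 heme genes without WT replicate 1, 10 and 3 without WT replicate 2, and 8 and 3 without KO replicate 2.

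Of 8 tested globin genes, 4 were lower and 1 higher, counts that were the same adjusted over the list alone. The embryonic zeta-like gene Hba-x rose 2.68-fold, from 129 ± 0.516 to 347 ± 82.4 CPM (SD, n = 2), while the embryonic beta-like gene Hbb-bh1 fell to 0.481 of WT. The adult gene Hbb-b1 fell from 15378 ± 2684 to 7033 ± 1114 CPM (SD, n = 2), a call lost without WT replicate 1 (edgeR adjusted p = 0.0640) and without KO replicate 2 (edgeR adjusted p = 0.0609). The list passed with a median of -0.81 (camera adjusted p = 0.0458; adjusted p = 0.436 with an estimated correlation), but not without WT replicate 1 (camera adjusted p = 0.0703) or KO replicate 2 (median -0.48, camera adjusted p = 0.102), and 1 member was lower in each of these fits. Without KO replicate 1 the median was -1.26.

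Markers of platelets, granulocytes, progenitors and mast cells had positive medians. Of 22 megakaryocyte and platelet genes, 16 were higher and 0 lower (19 higher adjusted over the list alone; median 0.58, camera adjusted p = 6.06e-08), among them Gp5, a platelet glycoprotein, from 20.8 ± 4.18 to 65.9 ± 10.8 CPM (SD, n = 2), and Alox12 (2.41-fold). Of 21 granulocyte genes, 11 were higher (13 higher and 1 lower adjusted over the list alone; median 0.77, camera adjusted p = 4.23e-05), with Mpo, myeloperoxidase, at 124 ± 9.40 in WT and 345 ± 28.2 CPM in KO (SD, n = 2), and Ltf at 2.93-fold. Of 31 stem and progenitor genes, 12 were higher and 3 lower (14 and 3 adjusted over the list alone; median 0.40, camera adjusted p = 0.00504). Esam rose 2.58-fold, Mycn 2.73-fold and Gata2 2.42-fold, while the 3 lower, chosen after their values were seen, were Flt3 (0.396 of WT), Lmo2 and Mllt3. Of 10 mast cell and basophil genes, 3 were higher, also over the list alone (median 0.52, camera adjusted p = 0.0174), among them Hdc at 2.31-fold, and this list did not pass without WT replicate 2 (camera adjusted p = 0.111). With an estimated correlation, adjusted p = 0.417 for each of these 4 lists. The higher members numbered 8 megakaryocyte genes without WT replicate 1 or KO replicate 1, 5 granulocyte genes without WT replicate 2 and 7 without KO replicate 1 (with 3 lower), and 7 stem and progenitor genes without KO replicate 2. The lower stem and progenitor genes numbered 1 without WT replicate 2 or KO replicate 2.

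The B lymphoid list had a negative median, and the T and NK list and the macrophage list did not pass. Of 14 B lymphoid genes, 4 were lower, also over the list alone (median -1.03, and -0.51 without WT replicate 1; camera adjusted p = 0.00294; adjusted p = 0.417 with an estimated correlation). They were Igll1, Vpreb1, Rag1 and Pou2af1, at 0.171, 0.0904, 0.362 and 0.270 of WT, all under 5 CPM in WT, and each of these calls was lost when at least 1 library was left out, for Pou2af1 whichever library it was (edgeR adjusted p up to 0.132); 1 member passed without WT replicate 1, KO replicate 1 or KO replicate 2. Of 7 tested T and NK genes, 0 passed by edgeR, DESeq2 or limma voom, and 0 adjusted over the list alone, with 2 higher and 1 lower at an unadjusted edgeR p under 0.05 (median 0.51, camera adjusted p = 0.588). The median was 0.89 without WT replicate 1, 0.19 without KO replicate 1 and 0.97 without KO replicate 2, where 1 was higher. They included Thy1 at 1.19 ± 0.0264 in WT and 2.30 ± 0.302 CPM in KO (SD, n = 2). Of 25 macrophage genes, 3 were higher and 3 lower, also over the list alone. The list did not pass (median -0.36, camera adjusted p = 0.1998, and 0.776 with an estimated correlation). It passed as lower without WT replicate 2 (camera adjusted p = 0.00191, 0 higher and 5 lower) and without KO replicate 1 (camera adjusted p = 0.0161, 3 higher and 6 lower), while its median was -0.05 without WT replicate 1 and -0.12 without KO replicate 2. Clec4f, a lectin of Kupffer cells, fell from 8.78 ± 1.02 to 1.10 ± 0.510 CPM (SD, n = 2; edgeR adjusted p = 0.00538) and Emr1, the F4/80 antigen, to 0.438 of WT, while Mertk, Siglec1 and Cd68 rose 1.61-fold, 2.28-fold and 2.13-fold; those 3 were chosen after their values were seen.

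Lists of hepatocyte, endothelial and stellate markers had positive medians. Of 39 hepatocyte genes, 15 were higher and 0 lower (27 higher adjusted over the list alone; median 0.77, and 0.48 without WT replicate 2; camera adjusted p = 1.52e-10), among them Ambp, from 568 ± 48.4 to 1187 ± 229 CPM (SD, n = 2), a call lost without WT replicate 2 (edgeR adjusted p = 0.0547), Ass1 (2.23-fold) and Fabp1 (1.78-fold). Albumin, Alb, was at 21421, 14945, 31296 and 24904 CPM and did not pass (edgeR adjusted p = 0.132). Of 23 endothelial genes, 14 were higher (17 adjusted over the list alone; median 0.60, camera adjusted p = 6.40e-09), with the sinusoid receptors Stab1 and Stab2 at 2.17-fold and 2.00-fold. With an estimated correlation, adjusted p = 0.417 for both lists. Of 30 stellate and mesenchymal genes, 11 were higher and 2 lower (13 and 2 adjusted over the list alone; median 0.36, camera adjusted p = 0.00120; adjusted p = 0.436 with an estimated correlation). Bgn, a matrix proteoglycan, rose 2.56-fold and Pdgfrb 1.98-fold, while Mgp fell to 0.195 of WT. The higher hepatocyte genes numbered 25 without WT replicate 1 and 5 without WT replicate 2, the endothelial genes 9 without WT replicate 1, and the stellate genes 5 without WT replicate 1 and 4 without WT replicate 2 or KO replicate 2.

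**Figure D3:**
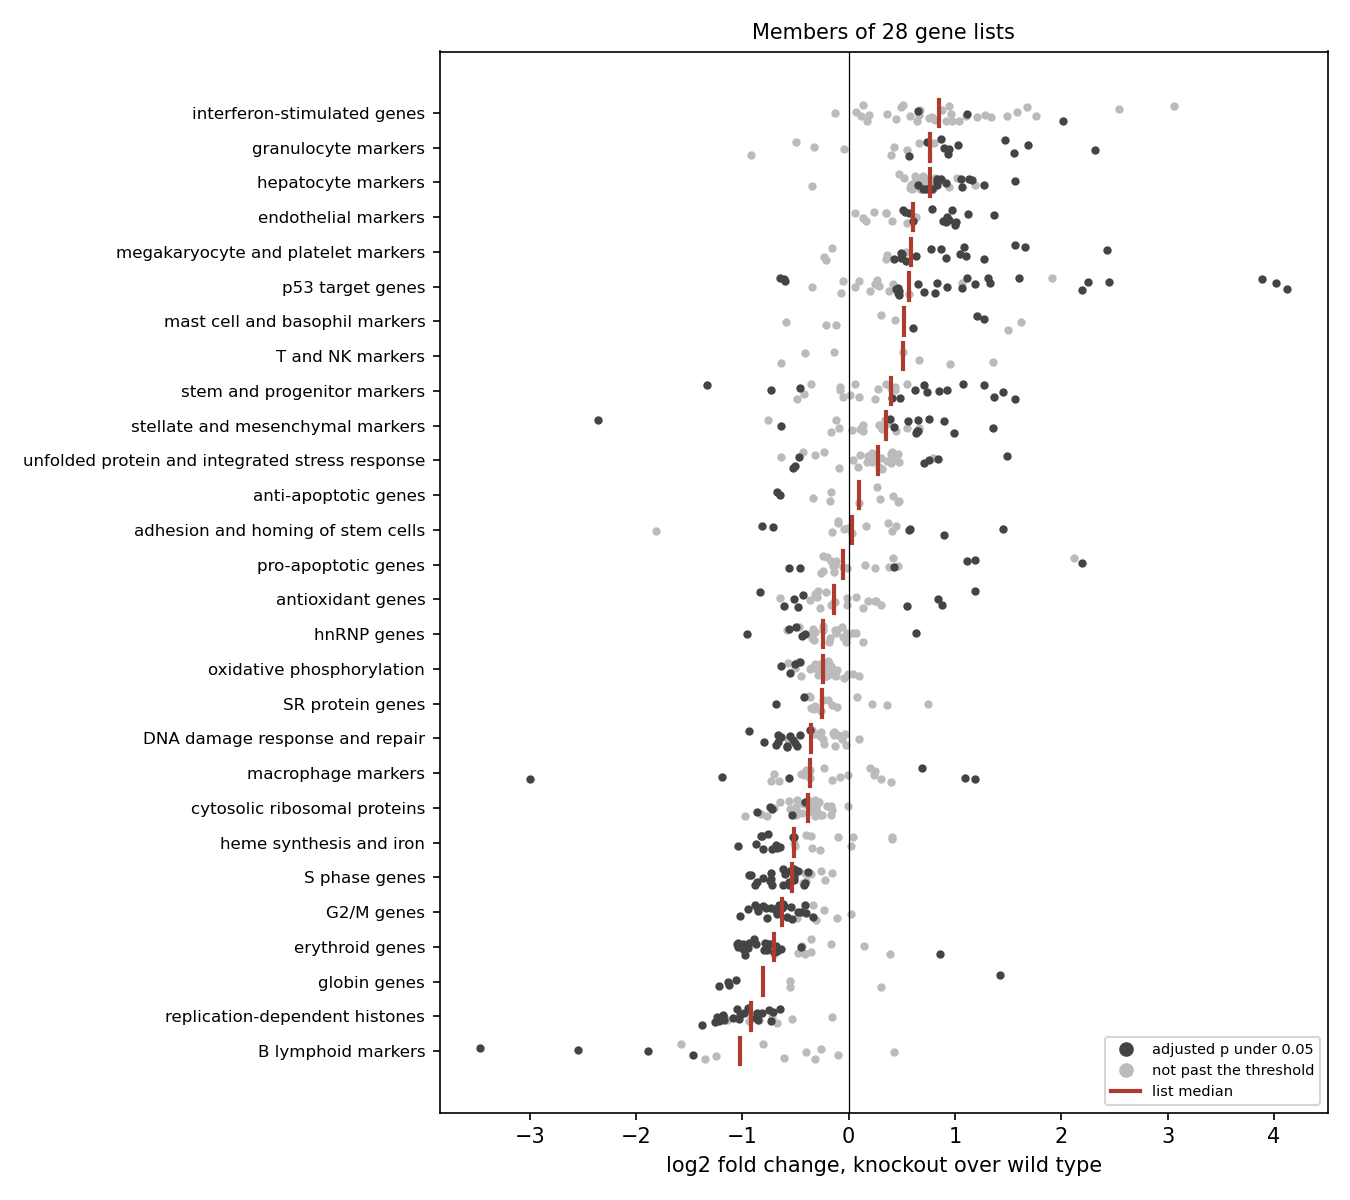
Log2 fold change, KO over WT (x), of the tested members of 28 gene lists (y), with dark points for members with an adjusted p under 0.05, grey points for the others and a red bar at the list median. The p53 list has a median of 0.57 with Cdkn1a at the far right, and the B lymphoid list a median of -1.03, which was -0.51 without WT replicate 1.

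The furthest falls were those of genes of heart muscle, which were present in the WT libraries and unevenly so. Of the 12 largest falls, 8 encode contractile or membrane proteins of cardiac muscle. Actc1, cardiac actin, had 18.3 and 135 CPM in the WT libraries against a mean of 2.34 ± 1.18 in KO (SD, n = 2), Tnnt2, cardiac troponin T, 4.92 and 30.7 against 0.230 and 0.371, and Myl4, an atrial myosin light chain, 17.2 and 22.6 against 0.543 and 0.819. Myl7 fell to 0.114 and Tnni1 to 0.0662 of WT. Tnni1 was lost without KO replicate 2 (edgeR adjusted p = 0.0527). WT replicate 2 carried much of the falls of Actc1, Tnnt2 and Tnni1. Without it the log2 fold change was -2.96 in place of -5.03 for Actc1, -4.02 in place of -5.88 for Tnnt2 and -2.32 in place of -3.92 for Tnni1. Myl4 and Myl7 did not rest on it: with any 1 library left out they stayed at -5.19 to -4.60 and -3.27 to -2.99. Without WT replicate 2, calls were lost for Myh7 (log2 fold change -1.46, edgeR adjusted p = 0.310), Pln (-2.31, edgeR adjusted p = 0.252) and Mybpc3 (-2.09, edgeR adjusted p = 0.105); these 3 were also lost without either KO library, with adjusted p of 0.0749 to 0.121. Of a list of 24 cardiac genes added after the data were seen, 18 were lower (19 adjusted over the list alone, median -4.48). Its camera adjusted p of 8.7e-09 (0.360 with an estimated correlation) adds no evidence, since the list was made with such genes in view. The other 4 of the 12 were Clec4f, Pld4, which fell from 35.3 ± 7.98 to 4.49 ± 1.96 CPM (SD, n = 2), Muc6 at 0.263 and AF251705 at 0.295 of WT.

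**Figure D4:**
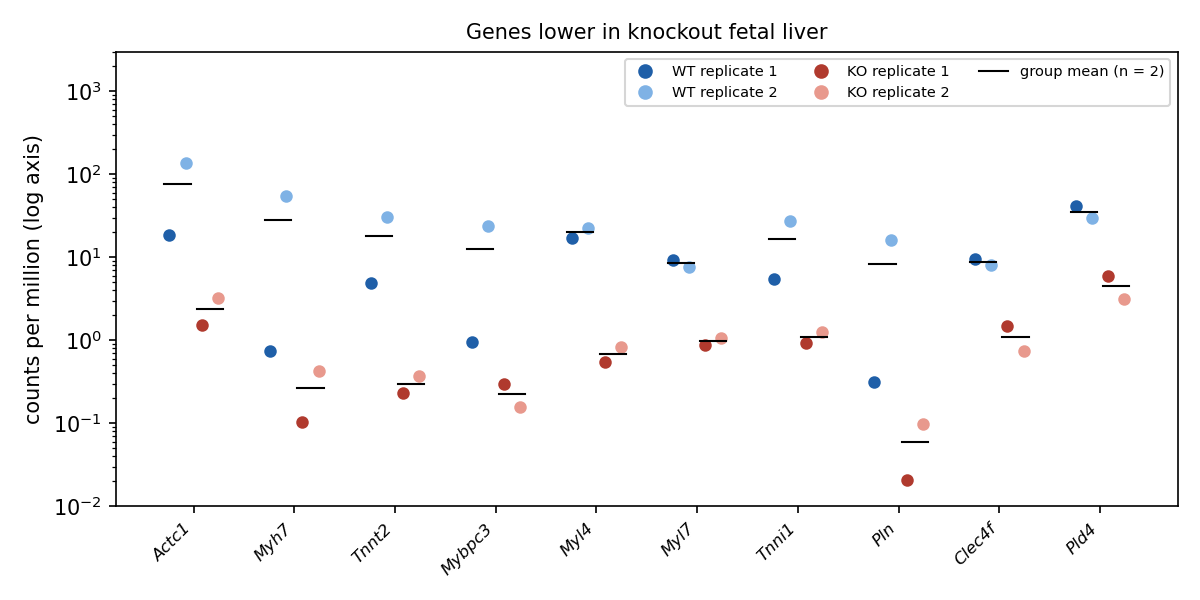
CPM (y, log axis) of 10 genes that were lower in KO (x), with 1 point per library and a bar at each group mean (n = 2). WT replicate 2 lies above WT replicate 1 for Actc1, at 135 against 18.3 CPM, and the Clec4f means are 8.78 CPM in WT and 1.10 CPM in KO.

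Among RNA-binding proteins, the hnRNP list had a median of -0.24 (camera adjusted p = 0.00112, and 0.417 with an estimated correlation). Over all genes 20.8% passed the gene test, a share to set beside the counts of this and the next 3 lists. Of 29 hnRNP genes, the targeted Hnrnpl among them, 5 were lower and 1 higher (7 and 1 adjusted over the list alone). Besides Hnrnpl these included Ptbp1, a repressor of exon inclusion, which was 1.55-fold higher, a call lost without WT replicate 1, WT replicate 2 or KO replicate 2 (edgeR adjusted p of 0.0684 to 0.0804). Of 16 SR protein genes, 2 were lower, and 1 adjusted over the list alone (median -0.25, camera adjusted p = 0.0141; adjusted p = 0.439 with an estimated correlation), and the list did not pass without WT replicate 2 (camera adjusted p = 0.119). Srsf10 was at 0.624 of WT, a call lost without KO replicate 2 (edgeR adjusted p = 0.0509). Of 39 cytosolic ribosomal protein genes, 5 were lower, and 1 adjusted over the list alone (median -0.39, camera adjusted p = 1.81e-07), with Rps20 at 0.551 of WT, a call lost without KO replicate 2 (edgeR adjusted p = 0.0505). Of 36 genes of oxidative phosphorylation, 4 were lower, and 2 adjusted over the list alone (median -0.24, camera adjusted p = 1.96e-05), with Cox6c at 0.645, likewise lost without KO replicate 2 (edgeR adjusted p = 0.0614). With an estimated correlation, adjusted p = 0.417 for both of these lists. The lower members numbered 1 hnRNP gene, 2 ribosomal and 1 oxidative phosphorylation genes without WT replicate 1, 1, 3 and 1 without WT replicate 2, 3, 10 and 9 without KO replicate 1, and 2, 0 and 0 without KO replicate 2. Lower SR protein genes numbered 1 without WT replicate 1, 1 without WT replicate 2 and 0 without KO replicate 2.

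The remaining lists hold interferon, stress, cell death, antioxidant and adhesion genes. Of 36 interferon-stimulated genes, 3 were higher, and 0 adjusted over the list alone (median 0.85, camera adjusted p = 0.00272; adjusted p = 0.678 with an estimated correlation). This list rested mainly on KO replicate 1, without which its median was -0.14. Its median was 1.15 without WT replicate 1, 0.58 without WT replicate 2 and 1.39 without KO replicate 2. At an unadjusted edgeR p under 0.05, 11 members were higher, and DESeq2 passed 7 and limma voom 1. Of 32 genes of the unfolded protein and integrated stress response, 4 were higher and 3 lower (5 and 3 adjusted over the list alone; median 0.27, camera adjusted p = 0.0344; adjusted p = 0.460 with an estimated correlation), which was lost without WT replicate 2 (camera adjusted p = 0.184) and KO replicate 1 (camera adjusted p = 0.115); Ddit4 rose 2.81-fold. Of 23 pro-apoptotic genes, 4 were higher and 2 lower, also over the list alone; the list did not pass, and its median of -0.05 and its test differed in sign (camera direction up, adjusted p = 0.769). Of 11 anti-apoptotic genes, 0 were higher and 2 lower, also over the list alone (median 0.10, direction down, camera adjusted p = 0.613). Of 27 antioxidant genes, 4 were higher and 5 lower, also over the list alone (camera adjusted p = 0.213), with Gstm1 at 2.28-fold. Of 17 genes of stem cell adhesion and homing, 4 were higher and 2 lower (5 and 3 adjusted over the list alone; camera adjusted p = 0.353), with Itgb2, an integrin of leukocytes, at 2.74-fold and Itga5 at 1.86-fold. With WT replicates 1 and 2 and KO replicates 1 and 2 left out in turn, the higher and lower members were 1 and 1, 2 and 0, 5 and 2, and 3 and 0 for the stress response. For pro-apoptotic genes they were 2 and 0, 2 and 0, 2 and 1, and 2 and 0 (median 0.11 without WT replicate 1), and for anti-apoptotic genes 0 and 1, 0 and 1, 1 and 2, and 0 and 0 (median -0.07 to 0.15). For antioxidant genes they were 2 and 0, 1 and 1, 2 and 4, and 1 and 0, and for adhesion genes 3 and 0, 3 and 1, 2 and 2, and 4 and 0 (median -0.05 to 0.08). In all, 22 of 28 lists passed camera with the preset correlation and 0 with an estimated correlation (1 at an unadjusted p under 0.05). With fry 3 passed (p53 targets, stem and progenitor, endothelial), each at adjusted p = 0.0420. The losses with an estimated correlation do not measure correlation alone, since with 4 libraries that test has few degrees of freedom. The endothelial list had an estimate of 0.0149, near the preset 0.01, yet its unadjusted camera p rose from 1.37e-09 to 0.0284. For hnRNP genes, with an estimate of -0.016, it rose from 0.000562 to 0.0598. A list lost in this way is thus not shown to owe its call to correlated members.

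Junction usage asked whether splicing differed. Of 105454 junctions in 10696 genes, 10 passed the diffSpliceDGE test of edgeR, 4 of them known and 6 putative; 3561 had an unadjusted p under 0.05, and the Simes test passed 8 genes. In Gpi1, glucose-6-phosphate isomerase, the junction from 35012256 to 35013947 on chromosome 7 held 8.97% and 9.89% of the gene's junction reads in the WT libraries (89 and 217 reads) and 0.541% and 0.136% in the KO libraries (13 and 4 reads), with a log2 usage change of -4.87 (edgeR adjusted p = 4.43e-20). In Haus5, a gene of the mitotic spindle, the junction from 31446807 to 31446888 held 6.67% and 8.44% in WT and 0.254% in KO replicate 1, with 0 of 428 reads in KO replicate 2, which allows a share of up to 0.701% (log2 usage change -5.64, edgeR adjusted p = 1.13e-05; adjusted p = 0.0923 without KO replicate 2). In Blvrb, biliverdin reductase B, the junction from 28244439 to 28244582 held 0.623% and 1.33% in WT and 3.75% and 3.83% in KO (log2 usage change 1.97, edgeR adjusted p = 0.00315), a call lost without WT replicate 1 (adjusted p = 0.870), KO replicate 1 (adjusted p = 0.119) or KO replicate 2 (adjusted p = 0.0519). The fourth known junction lay in the Y-linked gene Uty, whose reads came mostly from the male KO replicate 2 (338 reads, against 10, 16 and 12 in the other libraries), and its call was lost without KO replicate 1 (adjusted p = 0.192) or KO replicate 2 (adjusted p = 1.00), and with the replicate block (adjusted p = 0.203). Most of the 6 putative junctions had reads in 1 library only, such as Card10 with 933 reads in KO replicate 1. The count was 22 without WT replicate 2 (7 of the 10 among them) and 2 with limma diffSplice. Of the 4 known junctions limma passed Gpi1 and not Haus5 (adjusted p = 0.9999), Blvrb (adjusted p = 0.0994) or Uty (adjusted p = 0.9999).

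The target genes with tested junctions were Ptprc, Hnrnpl, Hnrpll, Casp9, Tjp1, Cd44, Mdm2 and Mdm4. They were named because hnRNP L or its paralog is known to control their splicing or because they act on p53. Of 123 tested junctions in these 8 genes, edgeR passed 0 over all junctions and 0 adjusted over the list alone. At an unadjusted edgeR p under 0.05 there were 3, the smallest p being 0.00534 in Ptprc. By limma diffSplice 0 passed in either way and 2 had an unadjusted p under 0.05, and without KO replicate 1 edgeR passed 1 adjusted over the list alone. Ptprc encodes CD45, whose variable exons 4 to 6 are skipped in some cells. The junction that skips all 3 (chromosome 1, 140013602 to 140022880) had 3 of 4, 6 of 6, 1 of 6 and 0 of 5 reads leaving the upstream exon in WT replicates 1 and 2 and KO replicates 1 and 2. These shares were 75.0% (95% Wilson interval 30.1 to 95.4), 100% (61.0 to 100), 16.7% (3.01 to 56.4) and 0%, which allows up to 60.0%. Pooled, 9 of 10 WT reads and 1 of 11 KO reads skipped (two-sided Fisher's exact test, p = 0.000346, which compares these libraries and not the genotypes). Among reads entering the exon after the variable exons, a count chosen after the values were seen, 3 of 10, 6 of 8, 1 of 10 and 0 of 11 came from this junction, the last allowing up to 27.3% (pooled 9 of 18 in WT and 1 of 21 in KO, two-sided Fisher's exact test, p = 0.00223, which likewise compares these libraries). The 6 junctions that include a variable exon, 2 of them putative, had 8, 5, 27 and 34 reads, while the level of Ptprc was 40.8, 32.8, 40.9 and 34.9 CPM. The 3 target junctions below an unadjusted 0.05 by edgeR all lay at these variable exons. Of them, 2 include a variable exon and rose, with log2 usage changes of 3.25 and 3.39. The other is the junction that skips the exons, and it fell, at -3.03. Each had fewer than 40 reads, the fewest among the simulated changes, so the missing calls do not show unchanged usage.

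Putative junctions took 3.03% and 0.725% of junction reads in the WT libraries and 0.667% and 0.643% in the KO libraries. The difference in means, KO minus WT, was -1.22 percentage points (exact two-sided permutation test, p = 0.333, the smallest that 2 against 2 allows) and rested on WT replicate 1: it was -0.07 without that library and -2.37 without WT replicate 2. In WT replicate 1, 103005 reads lay on a junction of Speer6-ps1, which had 9 reads in WT replicate 2 and 0 in both KO libraries.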

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

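The tests with the longest transcript per gene, with junctions compared only at a shared splice site and without Speer junctions were chosen only after the results were seen. Over all genes, edgeR called 3130 genes, and 3099 to 4341 under another scaling, no filter on low counts, the block, DESeq2, limma voom, the longest transcripts or without globin genes. Leaving out 1 library gave 1022 to 2492 genes, with fewer samples in the fit; 926 of the 3130 were also called without KO replicate 2 and 2083 without KO replicate 1. The fall of Hnrnpl passed under every alternative run, at log2 fold changes of -1.14 to -0.74. Of 113 named genes, 75 had the same call in each fit that left out a library and 38 changed in at least 1. In these fits the lone sample of a group is assumed to vary like the other group. No named gene, list or junction reversed in the direction of its test under the alternatives run, although medians changed sign for interferon genes without KO replicate 1 (-0.14), for pro-apoptotic genes without WT replicate 1 (0.11), for anti-apoptotic genes without WT replicate 1, WT replicate 2 or KO replicate 2 (-0.07 to -0.06) and for adhesion genes without WT replicate 1 (-0.03) or KO replicate 1 (-0.05).

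With an estimated correlation 0 of 28 lists passed. Endothelial genes were lost at an estimate of 0.0149, near the preset 0.01, so these losses do not measure correlation alone. With so few libraries, camera with an estimated correlation has few degrees of freedom and can pass few lists. With fry, which does not compare a list with other genes, 3 passed, and with the preset correlation 22. Leaving out 1 library gave 19 to 21. The call counts of junctions were 10 as planned, 6 at 20 reads or more per junction, 2 with limma diffSplice and 3 at shared splice sites. They also changed with 1 library left out. The cause of these changes was not tested. The junctions of the listed target genes gave 0 over all junctions with edgeR as planned (3 at an unadjusted p under 0.05), with the block and with limma diffSplice (2 at an unadjusted p under 0.05). They were not counted at other minimum counts or at shared splice sites. The difference in the putative share was -2.37 to -0.07 with 1 library left out, -1.17 at 10 reads or more per junction and -0.118 without Speer junctions.

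The number that file names share puts the libraries into 2 pairs, but nothing states what it marks, and the correlation of deviations within a pair was 0.134 across genes. With this replicate block edgeR called 4341 genes, 22 lists, 7 junctions and 0 target junctions, with Hnrnpl at -0.94; among the named genes, lists and junctions, 142 kept their call. Ifi44 (adjusted p = 0.0493) and Srsf3 (adjusted p = 0.0339) were now past the threshold and the Uty junction was no longer (adjusted p = 0.203). Alternatives for normalized values were not run, since the tables hold counts. In simulated data 26% of 4-fold usage changes were found at 40 to under 400 reads, and 2% of 2-fold changes at 400 reads or more.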

Other observations

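The questions of this part, except that of strain DNA near Hnrnpl, were chosen only after the result was seen. The p53 list and the fits without 1 library, used again here, were planned. Of 9 tested members of the eosinophil list, 2 were higher (3 adjusted over the list alone), Epx at 4.58-fold and Alox15 at 1.90-fold, with a median log2 fold change of 0.69 (camera adjusted p = 0.0105; adjusted p = 0.373 with an estimated correlation). Prg2, an eosinophil granule protein gene, was at 92.9 ± 12.1 CPM in WT and 124 ± 36.2 CPM in KO (SD, n = 2; edgeR adjusted p = 0.167). Of 11 skeletal muscle genes, 1 was lower, Mylpf, also over the list alone (median -0.87, camera adjusted p = 0.0202; adjusted p = 0.360 with an estimated correlation). The camera p-values of the eosinophil and skeletal muscle lists add no evidence, since these lists were added after the data were seen. They were adjusted over the added lists only.

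Of 39 p53 targets, 22 were higher in KO (14 without WT replicate 1), and so were 79 markers from 7 cell-type lists, so a changed mix of cells may contribute. It stays open: 31.82% of the 22 higher p53 targets (95% Clopper-Pearson interval 13.9 to 54.9) lay above the 95th percentile, 1.57 on the log2 scale, of those 79 markers, but both sets hold only genes already called as higher, so this share decides nothing. The sex of KO replicate 2 is argued against, since without that library the median of the list was 0.6484 on the log2 scale, against 0.57 with it. The call of the list over all libraries was lost with an estimated correlation (camera adjusted p = 0.417). That test has few degrees of freedom here, so this loss decides little. The mix of cells, the slides and the loss of hnRNP L itself stay open.

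Of 24 cardiac genes, 18 were lower in KO, and 22 were higher in WT replicate 2 than in WT replicate 1. Heart tissue carried along with the WT livers is a candidate explanation that stays open: the median absolute log2 ratio between the WT libraries was 2.084 over these genes, but the list was made after this unevenness was seen, so the value decides nothing. For skeletal muscle as the source, its list had a median 3.614 higher on the log2 scale than the cardiac list. This gap decides nothing either, since the cardiac list was made after the data were seen. By itself the skeletal list had 1 of 11 genes lower and a median of -0.87. Of the 24 cardiac genes, 6 had at least 1 CPM in both KO libraries, among them Tnnc1 at 10.2 and 6.07 CPM. An effect of hnRNP L on these genes in liver cells was not tested.

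Of the 4 known junctions called, 3 lay within 10 Mb of Hnrnpl (Blvrb at 1.36 Mb, Haus5 at 1.84 Mb and Gpi1 at 5.39 Mb), a window that holds 173 of the genes with tested junctions against 10523 elsewhere. DNA of another strain kept around the targeted gene may change splice sites there. Among genes without a call, a Simes p under 0.05 was found in 7 of 168 genes in the window and 414 of 10519 elsewhere (odds ratio 1.061, 95% interval 0.417 to 2.26, one-sided Fisher's exact test, p = 0.495). The interval is too wide to decide, and strain DNA and an effect of hnRNP L cannot be told apart for these 3 junctions without the sequence of the region.

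A junction joining the first and seventh annotated exons of Hnrnpl (29596187 to 29603480), which skips 5 exons between, had 0, 0, 2 and 1 reads in WT replicates 1 and 2 and KO replicates 1 and 2. In WT replicate 1, putative junctions of Speer2 and Speer3 had 4383 and 4305 reads, and those of the other libraries had at most 1.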
